A study of Caenorhabditis elegans with 4 samples.

How the data were processed

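RNA of wild-type Caenorhabditis elegans L2 larvae (4 preps, 1 array each) was measured on 2-colour arrays against a mixed wild-type reference, per the labels. The values used are log2 ratios as deposited by the authors in the series' value table. That the base is 2 was settled from the values: 2 to the power of a value was within 0.05 of a whole number of thousandths for 100% of the ratios below 0.9 on each array, so the authors had rounded ratios to 3 decimals, which is coarse for the lowest ratios (0.004, 0.006, 0.015 and 0.004 for preps 1 to 4). The deposited medians were 0.0158, 0.0580, 0.0552 and 0.0186 and the SDs 0.924, 1.02, 0.795 and 0.712. The authors' background correction, normalization and spot filters are not given in the sources used here, nor are the dyes, so scale and centring were known from the values only and direction stays likely. Intensities were not used here, so neither an intensity-dependent normalization nor a filter on dim spots could be applied. A dye bias cannot be separated from L2, since the labels name no dye swap.

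Probe names came from the platform's annotation. Of 21632 probes, 16450 had 1 gene, 247 several and 4935 were unnamed. By gene ID, 16360 of the first kind matched a newer gene table (assembly WBcel235), with 0 changed symbols, and 90 kept the older symbol. No coordinates are printed, since the array's build is not given in the sources used here. Probes of a gene were averaged per array, and probes with several genes or unnamed stayed as probes. Among 1453 genes with more than 1 tested probe, 1 had probes past the threshold in opposite directions, 114 had all and 206 some of their probes past it in the same way. The mean ratios of a pair of probes correlated at r = 0.730 across genes. Near-identical genes, such as the major sperm protein and histone genes, cannot be told apart by hybridisation, so their counts are not counts of independent genes.

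Each array was centred on its median over all probes. Features on at least 3 arrays were tested with limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided) as the mean log2 ratio against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. This treats the reference as 1 control sample and leaves out its own spread. Gene lists were fixed before the data were examined and tested on features present on all 4 arrays with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over 34 lists. Leaving aside the X chromosome list, whose overlaps were not counted, a few genes belong to more than 1 list, at most 4 for any pair of lists. Counts adjusted over the list alone use the same p-values with the adjustment within the list.

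Named genes followed a rule fixed before the data were examined, for features with 1 gene name on all 4 arrays. They are the 12 highest and 12 lowest means among genes past the threshold with the same sign on all 4 arrays. Added are, for each list except the X chromosome, the 2 highest and 2 lowest members past the threshold (or, where none passed, the 1 with the largest absolute mean), and every measured vitellogenin and heterochronic gene. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

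The fit was tested on simulated data with 200 changed features among 19941. It recovered 0% of those changed by 0.5, 26% by 1, 70% by 2 and 96% by 4 on the log2 scale, with 2 unchanged features among 98 called. The adjustment depends on the share of changed features, so these rates need not hold in the data, where 2936 features were called. With camera, a simulated list of 30 genes shifted by 0.5 was called and an unshifted one was not. The simulated genes were drawn independently of each other, whereas real lists had estimated correlations of up to 0.815 (abu genes). This test therefore does not measure false list calls in the data.

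Alternatives were deposited values without centring, mean centring, scale and quantile normalization, array weights, a robust fit, a test against a fold of 1.5, other minimum numbers of arrays, single probes, a filter on ratios above 6 in size on the log2 scale, the month of the array's date as a random block, and leaving out each prep in turn. Centring within the 32 runs of 676 neighbouring probes and a restriction to features with 1 gene name were added after seeing the data.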

Results

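Transcript levels were measured in second-stage (L2) larvae of wild-type Caenorhabditis elegans, a stage with a small, growing germ line and no eggs or sperm. In all, 4 RNA preparations (preps 1 to 4) of wild-type L2 larvae were each hybridised on a separate 2-colour DNA array together with a mixed wild-type reference RNA. What had been mixed in the reference is not given in the sources used here. All 4 arrays form 1 group, so the comparison of L2 with the reference is the only one the design holds, and each value is a log2 ratio. The labels place the reference in channel 1 and L2 in channel 2, but name no dyes. Positive ratios are therefore read as likely higher in L2, from this order of channels, and every direction given here rests on that reading. Yolk and sperm protein genes had been set beforehand as a check of it. Their list medians were -5.42 and -3.19, and negative in all 4 preps. L2 larvae have no sperm and yolk proteins are made by the adult intestine, so these lists argue against the turned reading. Their low values are for this reason not a separate result. Of 21632 probes, 21305, 21227, 21386 and 21209 had a value in preps 1, 2, 3 and 4, and 20570 had one on all 4 arrays. No spot intensities were used, so the number of arrays limits the precision.

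The gene with the lowest mean was ule-3, named for its product in the uterine lumen, at a log2 ratio of -6.01 ± 1.2 (SD, n = 4), or 64.5-fold lower in L2. It was followed by the yolk protein gene vit-2, and the eggshell genes perm-2 (-4.79 ± 1.02) and cpg-2 (-4.68 ± 0.86) were also among the 12 lowest, with ule-4, stha-3, col-36, D1054.10, ZK813.1 and ZK813.3. D1054.10 varied little, at -5.34 ± 0.17. At the other end stood the infection response genes irg-5 (4.76 ± 2.40, or 27.2-fold higher) and irg-4 (4.31 ± 2.07), the cytochrome P450 gene cyp-35A3 (3.71 ± 1.86) and the UDP-glucuronosyltransferase genes ugt-13, ugt-8, ugt-12 and ugt-63. Smaller spreads were seen for cpr-5, a cathepsin B-like protease gene (3.22 ± 0.28), ugt-12 (3.25 ± 0.48), dod-19 (3.13 ± 0.42) and phat-7, a toxin-related gene of the pharyngeal glands (3.13 ± 0.33), and bah-1 and the cuticlin gene cut-2 complete the 12 highest.

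**Figure D1:**
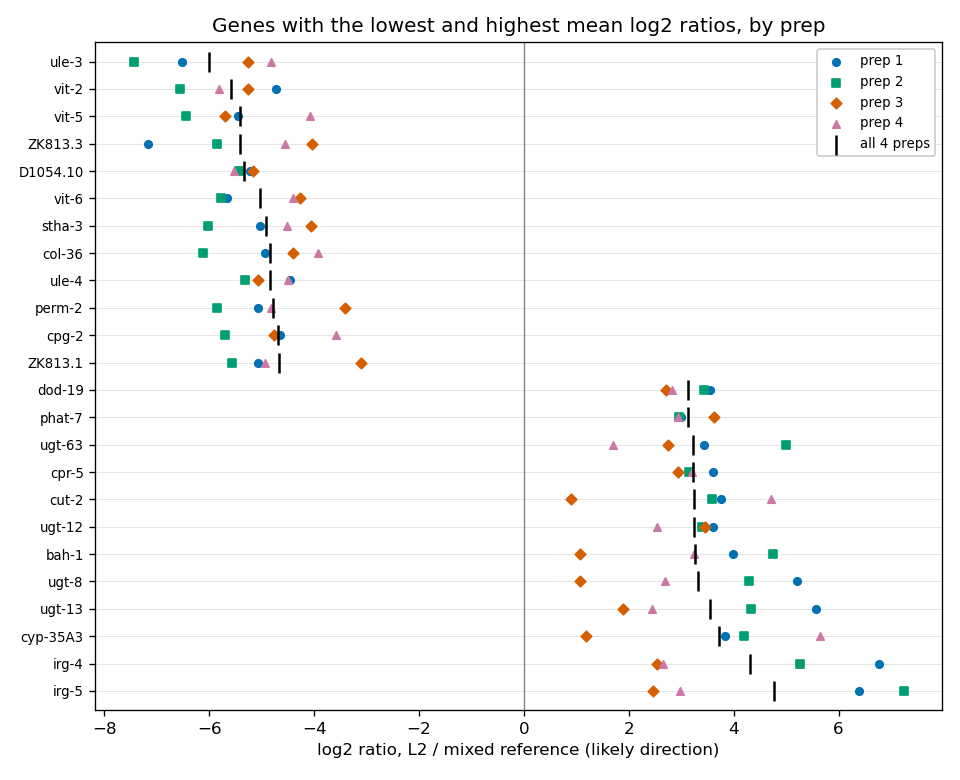
Log2 ratio of L2 over the mixed reference (horizontal axis, direction likely) for the 12 genes with the lowest and the 12 with the highest mean, 1 symbol per prep and a vertical bar for the mean of the 4 preps. All 4 preps lie on the same side of 0 for each gene, as the naming rule required, and irg-5 ranges from 2.46 in prep 3 to 7.24 in prep 2.

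Of 19941 features tested with limma (genes, and probes without a single gene name), 2936 had an adjusted p under 0.05, of which 968 were higher and 1968 lower in L2. Among those past the threshold, 528 were at least 2-fold higher and 1226 at least 2-fold lower, and at least 10-fold changes numbered 6 and 101. The 14921 features with 1 gene name held 2478 of the calls, 795 higher and 1683 lower. The counts depended on the number of preps: 1157 features passed without prep 1 (285 higher, 872 lower), 1204 without prep 2 (325 and 879), 3202 without prep 3 (1362 and 1840) and 1699 without prep 4 (492 and 1207). Of 103 named genes past the threshold, 67, 68, 95 and 79 were still past it without preps 1, 2, 3 and 4, with 0 changes of sign. Against a fold of 1.5 in place of 0, 43 of the 103 were no longer past it. Among the 24 genes above, 6 calls ended in the fits without 1 prep: cut-2 without prep 1 (adjusted p = 0.0549), and without prep 2 irg-4 (0.0542), cyp-35A3 (0.0602), ugt-13 (0.0549), ugt-8 (0.0772) and cut-2 (0.0632). Against a fold of 1.5 the call of ugt-8 ended as well (adjusted p = 0.0578). The labels do not say that the preps came from separate cultures, so each p measures the spread between these samples, which may be technical, and leaves out the spread of the reference.

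Genes of oocytes, yolk and sperm were low together, though the yolk and sperm lists served as the check of direction and are no separate result. All 3 measured vitellogenins, the yolk proteins made by the adult intestine, fell: vit-2 to -5.59 ± 0.78, vit-5 to -5.42 ± 0.99 and vit-6 to -5.03 ± 0.80. Of 30 major sperm protein genes, which encode the cytoskeletal protein of the crawling sperm, 28 fell and 0 rose (29 fell adjusted over the list alone), with msp-33 at -4.35 ± 0.80 and msp-78 at -4.23 ± 1.06. Of 34 oocyte and maternal genes 30 fell and 0 rose (32 and 0 adjusted over the list alone), led by perm-2 and cpg-2. The median log2 ratios were -5.42, -3.19 and -2.90 for these 3 lists. In prep 3 the median of the sperm proteins was -2.44, the nearest to 0 of the 4 preps. A wider list of sperm formation genes had 7 of 35 lower and 0 higher (9 and 1 adjusted over the list alone), with a median of -0.33, and its lowest members were nspd-6 (-2.16 ± 0.73) and nspd-5 (-2.01 ± 0.32). Its count was 3, 3, 9 and 5 without preps 1, 2, 3 and 4.

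Of 41 genes of germ line proliferation and meiosis, 28 fell and 0 rose (33 and 0 adjusted over the list alone), among them the translational repressor gld-1 (-2.27 ± 0.54) and htp-1, a protein of the meiotic chromosome axis (-2.24 ± 0.29). The median was -0.93, and 17, 17, 24 and 21 members fell without preps 1, 2, 3 and 4. DNA replication and cell cycle genes were also lower, with 34 of 71 lower and 0 higher (51 and 1 adjusted over the list alone) and a median of -0.69. The B-type cyclin genes cyb-3 (-2.75 ± 0.69) and cyb-1 (-2.13 ± 0.22) were its lowest, and 17, 15, 29 and 29 members fell without preps 1, 2, 3 and 4. All of these 6 lists shifted down against the other genes in camera with a preset correlation (adjusted p from 1.24e-23 to 0.00582). With an estimated correlation 0 of them did, at adjusted p = 0.488 for the vitellogenin, sperm protein, oocyte and germ line lists, adjusted p = 0.515 for the cell cycle list and adjusted p = 0.658 for sperm formation. By fry, all of them but sperm formation (adjusted p = 0.116) passed, at adjusted p from 0.0119 to 0.0421. Histone genes had 5 of 55 lower and 0 higher (0 adjusted over the list alone) and did not shift (adjusted p = 0.0851), except with centring within runs of neighbouring probes, a setting added after seeing the data (adjusted p = 0.0491; with an estimated correlation and no run centring, adjusted p = 0.658), with his-24 at -0.94 ± 0.59 and his-74 at -0.88 ± 0.26. The histone count was 0, 0, 3 and 1 without preps 1, 2, 3 and 4, and his-24 passed only without prep 4 (adjusted p = 0.0224) and his-74 only without prep 3 (0.0364). The call of his-24 also ended with deposited values (0.0502), mean centring (0.0548), run centring (0.0923) and array weights (0.0608). Embryonic patterning genes did not shift either (adjusted p = 0.585), with 2 of 37 lower (1 adjusted over the list alone): pal-1, whose transcript is supplied by the mother (-2.14 ± 0.55), and sdz-28 (-0.88 ± 0.48). The count of 2 was 1 without prep 1, 2 or 3, and sdz-28 lost its call without any prep (adjusted p = 0.105, 0.0989, 0.06 and 0.0708) and with run centring (0.1).

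**Figure D2:**
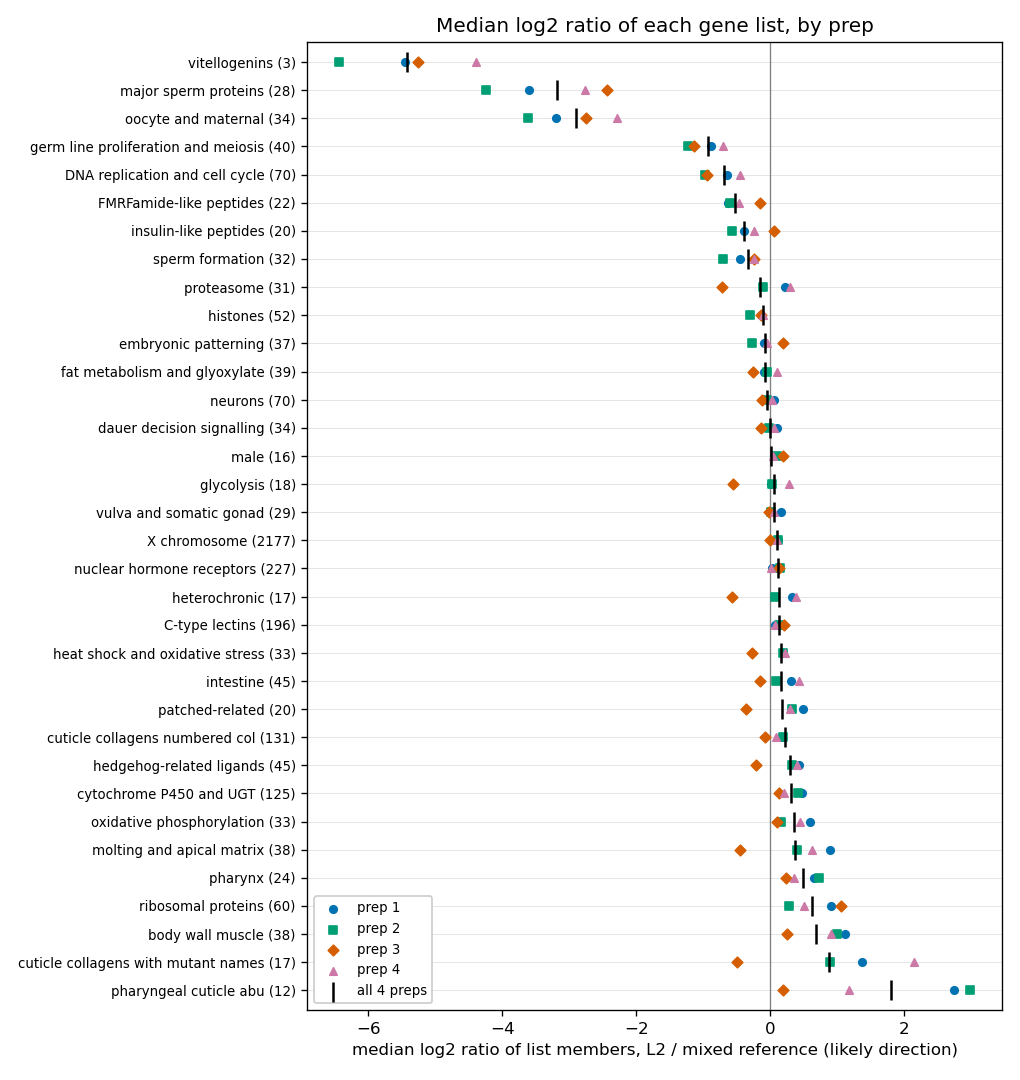
Median log2 ratio of L2 over the mixed reference (horizontal axis, direction likely) of the members of each of 34 gene lists, with the number of members on all 4 arrays in brackets, 1 symbol per prep and a vertical bar for the median of the 4-prep means. The vitellogenin list is lowest at -5.42 and the pharyngeal cuticle list highest at 1.80, and prep 3 lies apart for the mutant-named collagens at -0.51 and the molting genes at -0.45.

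Cuticle genes moved in both directions. Of 134 numbered collagen genes 30 rose and 32 fell (45 and 39 adjusted over the list alone), with col-149 (2.65 ± 0.46) and col-154 (2.39 ± 0.82) the highest and col-36 (-4.84 ± 0.94) and col-140 (-4.31 ± 0.58) the lowest. The median was 0.22, the mean -0.19, and the list did not shift (adjusted p = 0.693). The rises numbered 13, 13, 34 and 27 without preps 1, 2, 3 and 4. Of 17 collagens named after mutants 3 rose and 1 fell (5 and 1 adjusted over the list alone), with dpy-5 at 2.18 ± 1.62, dpy-13 at 2.05 ± 1.51 and dpy-17 at -2.17 ± 1.66. Their rises numbered 0, 1, 8 and 1 without preps 1, 2, 3 and 4. The calls of dpy-5 (0.145, 0.161 and 0.119) and dpy-13 (0.145, 0.151 and 0.124) ended without prep 1, 2 or 4, and that of dpy-17 without prep 1, 3 or 4 (0.155, 0.131 and 0.129). Ends of calls were also seen for dpy-13 with scale (0.0638) and quantile normalization (0.0554), and for dpy-17 with deposited values (0.0527), mean centring (0.055), scale normalization (0.0505), run centring (0.0645) and a robust fit (0.0515). This list shifted up (median 0.88, adjusted p = 0.00672), but not with an estimated correlation (adjusted p = 0.673) or without prep 4 (adjusted p = 0.0853). Its median was -0.51 in prep 3 and between 0.90 and 2.14 in the others.

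Of 39 genes of molting and the apical matrix, 4 rose and 4 fell (6 and 5 adjusted over the list alone). The cuticlin genes went apart, with cut-2 high and cut-1 (-3.89 ± 0.77) and cut-3 (-3.15 ± 0.83) low. The astacin protease gene nas-36 was at 1.68 ± 1.09, and its call ended without prep 1, 2 or 4 (adjusted p = 0.117, 0.0953 and 0.0633) and with run centring (0.0559). The list did not shift with equal weights of the 4 preps (median 0.37, adjusted p = 0.114), but did with array weights (adjusted p = 0.0046). Without prep 3, whose median was -0.45, it also did (adjusted p = 0.000844), with 14 members higher. Over all 4 preps with an estimated correlation the adjusted p was 0.847. The rises were 0, 1 and 1 without preps 1, 2 and 4, and the falls 2, 2, 2 and 3 without preps 1, 2, 3 and 4. Hedgehog-related genes had 2 of 47 higher and 10 lower (8 and 10 adjusted over the list alone; adjusted p = 0.383). The lowest were grl-20 (-3.09 ± 0.47) and grl-17 (-2.96 ± 0.75), and the rises of grd-14 (1.89 ± 1.27) and grd-3 (1.17 ± 0.70) were not past the threshold without prep 1 (0.118 and 0.112) or 2 (0.132 and 0.0793), nor that of grd-14 without prep 4 (0.0736) or with run centring (also 0.0736). Hedgehog-related rises were 0, 0, 8 and 2 and falls 6, 7, 8 and 7 without preps 1, 2, 3 and 4. Of 22 patched-related genes 1 rose and 1 fell, ptc-1 (-1.07 ± 0.47), with the same counts adjusted over the list alone. The list did not shift (adjusted p = 0.333), but did without prep 3 (adjusted p = 0.0094), and with an estimated correlation over 4 preps had an adjusted p = 0.847. The call of ptc-1 ended without prep 2 (0.0681) or 4 (0.0564), and the list's rises were 0, 0, 4 and 0 without preps 1, 2, 3 and 4.

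Heterochronic genes, which set the timing of larval cell fates, gave 0 calls among 17 measured members, also adjusted over the list alone, and the list did not shift (median 0.13, adjusted p = 0.474). The lowest mean was that of hbl-1 (-0.90 ± 0.76, adjusted p = 0.0857) and the highest that of kin-20 (0.71 ± 1.14). Others were lin-29 at 0.50 ± 0.38, lin-41 at -0.36 ± 0.60, lin-42 at 0.15 ± 0.18, daf-12 at 0.33 ± 0.44 and apl-1 at -0.26 ± 1.04. At alg-1 the mean was 0.60, at let-418 0.46, at sea-2 0.42, at dre-1 0.27, at mab-10 0.13, at blmp-1 0.06, at alg-2 0.03, at lin-46 -0.01, at lin-66 -0.13 and at nhl-2 -0.58. In prep 3 the list's median was -0.57, against 0.07 to 0.38 in the others. Without prep 3 the list shifted up (adjusted p = 0.0241) and kin-20 (adjusted p = 0.00958), dre-1 (0.0355) and let-418 (0.0395) passed, and without prep 4 hbl-1 passed (0.0274). With an estimated correlation over 4 preps the list had an adjusted p = 0.847. With array weights over all 4 preps, alg-1 (0.0483) and kin-20 (0.0497) passed.

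Muscle and pharynx genes were high in L2. Of 38 body wall muscle genes 13 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.68. The titin gene ttn-1 was at 2.53 ± 0.32 over 3 probes, which differed in prep 3 (3.97, 0.68 and 3.62). The body wall myosin gene myo-3 was at 2.04 ± 1.06, and its call ended without prep 1, 2 or 4 (adjusted p = 0.066, 0.0754 and 0.0567). Of 24 pharynx genes 7 rose and 0 fell (10 and 1 adjusted over the list alone), with the gland gene phat-4 at 2.93 ± 0.98 and the pharyngeal myosin gene myo-2 at 2.23 ± 0.57. Of 13 abu genes, linked to the pharyngeal cuticle, 5 rose and 0 fell (10 and 0 adjusted over the list alone), with abu-15 at 2.54 ± 1.58 and abu-10 at 2.24 ± 1.31. These calls were lost without prep 1 (0.0896 and 0.0815) or 2 (0.104 and 0.0824), and abu-15 also without prep 4 (0.0592). All 3 lists shifted up (adjusted p from 1.3e-09 to 2.79e-05), and with an estimated correlation the muscle (adjusted p = 0.515), pharynx (adjusted p = 0.488) and abu (adjusted p = 0.61) lists did not. The rises without preps 1, 2, 3 and 4 were 8, 8, 25 and 10 for muscle, 4, 5, 9 and 6 for pharynx, and 0, 0, 12 and 2 for abu. Prep 3 had the lowest median of the 4 preps in each, at 0.25, 0.24 and 0.19.

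Intestine genes moved both ways, with 12 of 45 higher and 8 lower (15 and 13 adjusted over the list alone; adjusted p = 0.329). High were cpr-5 and the acyl-CoA dehydrogenase gene acdh-1 (2.78 ± 1.39; adjusted p = 0.0557 without prep 1), and low were the ferritin gene ftn-1 (-2.21 ± 0.65) and the metallothionein gene mtl-1 (-2.2 ± 0.61). The rises were 5, 8, 16 and 9 and the falls 5, 4, 8 and 6 without preps 1, 2, 3 and 4. Neuronal genes had 4 of 70 higher and 5 lower (3 and 4 adjusted over the list alone) and did not shift (adjusted p = 0.652). The lowest were tbh-1 (-2.82 ± 0.43) and tdc-1 (-2.30 ± 0.42), enzymes of octopamine and tyramine synthesis that are also made in the gonadal sheath. The highest, the touch neuron tubulin gene mec-7 (0.94 ± 0.23) and the dopamine enzyme gene cat-2 (0.94 ± 0.40), were not past the threshold without prep 1, 2 or 4 (adjusted p from 0.0508 to 0.102). The neuronal rises were 0, 0, 6 and 0 and the falls 3, 3, 4 and 3 without preps 1, 2, 3 and 4. FMRFamide-like peptide genes had 7 of 22 lower and 0 higher (12 and 0 adjusted over the list alone) and shifted down (median -0.53, adjusted p = 0.00333), but not with an estimated correlation (adjusted p = 0.669). Their falls were 0, 0, 7 and 1 without preps 1, 2, 3 and 4. The lowest, flp-15 (-1.21 ± 0.71) and flp-24 (-1.1 ± 0.47), were not past the threshold without prep 1, 2 or 4 (adjusted p from 0.0692 to 0.112) or with run centring (0.0621 and 0.0528). Vulva and somatic gonad genes had 2 of 30 higher (him-4 at 1.26 ± 0.75 and lin-2 at 0.55 ± 0.04) and 1 lower (gon-4 at -0.87 ± 0.49), with 0 adjusted over the list alone and no shift (adjusted p = 0.774). The rises were 0, 0, 2 and 0 and the falls 0, 0, 0 and 1 without preps 1, 2, 3 and 4, and lin-2 lost its call without any prep (adjusted p from 0.0559 to 0.158). With run centring him-4 (0.053), lin-2 (0.0918) and gon-4 (0.0592) were not past the threshold. Of 17 male genes 1 rose, trf-1 (0.84 ± 0.40), with 0 adjusted over the list alone and no shift (adjusted p = 0.474), and its call held only without prep 4 among the fits with 3 preps (adjusted p = 0.0456, and 0.0954, 0.123 and 0.0724 without preps 1, 2 and 3).

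Ribosomal protein genes were higher in L2, with 18 of 61 higher and 0 lower (37 and 1 adjusted over the list alone) and a median of 0.63. The named members were rpl-14 (1.31 ± 0.91), which lost its call without prep 1 (0.0955) or 2 (0.139) and with quantile normalization (0.0593), and rpl-11.2 (1.21 ± 0.35). The list shifted up (adjusted p = 2.79e-12), but not with an estimated correlation (adjusted p = 0.562), and its rises were 1, 9, 11 and 5 without preps 1, 2, 3 and 4. Oxidative phosphorylation genes had 2 of 34 higher and 4 lower (8 and 4 adjusted over the list alone). Their small upward shift (median 0.36, adjusted p = 0.0477) was absent with an estimated correlation (adjusted p = 0.673), without prep 1 (adjusted p = 0.19), without prep 4 (adjusted p = 0.143), with deposited values (adjusted p = 0.0531) and with mean centring (adjusted p = 0.0603). It was also lost with a robust fit (adjusted p = 0.168), with the month as a block (adjusted p = 0.156) and without the most extreme ratios (adjusted p = 0.0502). The cytochrome complex genes went apart, with ucr-2.2 at 1.2 ± 0.77 and ucr-2.3 at -1.21 ± 0.22, as did the succinate dehydrogenase genes sdhd-1 (0.72 ± 0.34) and sdha-2 (-1.15 ± 0.57). Of these 4, only ucr-2.3 passed without each prep in turn. Without prep 1 the adjusted p was 0.132 for ucr-2.2, 0.136 for sdhd-1 and 0.0629 for sdha-2, and the call of ucr-2.2 ended with scale (0.0634) and quantile normalization (0.051) as well. The rises were 0, 0, 7 and 0 and the falls 2, 1, 4 and 3 without preps 1, 2, 3 and 4. Proteasome genes had 1 of 31 lower, pas-7 (-0.97 ± 0.35), also adjusted over the list alone, and did not shift (adjusted p = 0.389). Its call ended without prep 1 (0.0696) or 4 (0.0522). Of 19 glycolysis genes 1 rose, pgk-1 (0.91 ± 0.49), and 2 fell, gpd-4 (-2.11 ± 0.43) and hxk-1 (-1.42 ± 0.47), with the same counts adjusted over the list alone and no shift (adjusted p = 0.988). Glycolysis rises were 0, 0, 2 and 0 without preps 1, 2, 3 and 4, and pgk-1 was not past the threshold with scale normalization (0.0555) or run centring (0.0907). The median of this list was 0.05 and its mean -0.12, and the median turned negative with run centring (-0.08) and without prep 1 (-0.09) or 4 (-0.12). Of 40 genes of fat metabolism and the glyoxylate cycle 9 rose and 13 fell (10 and 14 adjusted over the list alone; adjusted p = 0.585), with lbp-7, a lipid-binding protein gene, at 2.71 ± 0.83, and the acyl-CoA synthetase gene acs-2 (-3.04 ± 0.67) and the desaturase gene fat-3 (-2.79 ± 0.39) lowest.

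Some detoxification genes, mostly UDP-glucuronosyltransferase genes, were among the highest in L2. Of 129 cytochrome P450 and UDP-glucuronosyltransferase genes 27 rose and 7 fell (37 and 9 adjusted over the list alone), with cyp-35A3 and ugt-13 at the top and ugt-18 (-2.14 ± 0.89) and cyp-13A1 (-1.34 ± 0.75; adjusted p = 0.0879 without prep 1) at the bottom. The list shifted up (median 0.31, adjusted p = 4.05e-05), but not with an estimated correlation (adjusted p = 0.515). The rises were 10, 8, 29 and 20 and the falls 2, 3, 7 and 4 without preps 1, 2, 3 and 4. The 2 families were also tested apart by camera, among 183 families grouped by name after the data were seen. Of 62 ugt genes 18 rose and 1 fell, with an upward shift (median 0.48, adjusted p = 1.12e-06). Of 63 cyp genes 9 rose and 6 fell, without a shift (median 0.10, adjusted p = 0.224). With an estimated correlation neither family shifted (adjusted p = 0.756 for each). Heat shock and oxidative stress genes had 4 of 33 higher and 4 lower (6 and 6 adjusted over the list alone; adjusted p = 0.587). The small heat shock genes hsp-12.6 (-3.61 ± 0.62) and hsp-12.3 (-2.86 ± 0.61) were low. Higher were hsp-16.1 (1.78 ± 1.32), lost without prep 1, 3 or 4 (0.0908, 0.0759 and 0.0739), with run centring (0.0636) and with a robust fit (0.0503), and gst-5 (1.58 ± 0.86), lost without prep 1 or 2 (0.0553 and 0.0907). Stress gene rises were 0, 2, 7 and 2 and the falls 2, 3, 3 and 2 without preps 1, 2, 3 and 4. Of 203 C-type lectin genes 11 rose and 11 fell (11 and 10 adjusted over the list alone; adjusted p = 0.114), from clec-87 (-4.32 ± 0.40) and clec-91 (-4.11 ± 0.75) to clec-206 (1.80 ± 1.17) and clec-57 (2.23 ± 0.72). The call of clec-206 ended without prep 1, 2 or 4 (0.115, 0.0815 and 0.0555) and with run centring (0.0542). The rises were 3, 4, 12 and 6 without preps 1, 2, 3 and 4. Of 234 nuclear hormone receptor genes 11 rose and 9 fell (5 and 2 adjusted over the list alone; adjusted p = 0.189), including nhr-73 (2.27 ± 0.46), nhr-259 (1.58 ± 0.59), nhr-57 (-1.97 ± 0.32) and nhr-21 (-1.52 ± 0.90). The last was not past the threshold without prep 1, 2 or 4 (0.0978, 0.0927 and 0.065), with scale normalization (0.0646) or with run centring (0.0515). The rises were 5, 4, 9 and 4 and the falls 2, 2, 9 and 3 without preps 1, 2, 3 and 4.

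Of 34 genes of dauer decision signalling, which governs entry into the arrested larva, 4 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.811). Higher were daf-22, a thiolase of pheromone synthesis (2.03 ± 0.84), and daf-36, an enzyme of steroid hormone synthesis (1.38 ± 0.34). Lower were the phosphatase gene daf-18 (-2.27 ± 0.32) and the kinase gene akt-1 (-1.37 ± 0.68), the latter not past the threshold without prep 1 (0.0614) or 2 (0.0837). The median was 0.00 and took either sign with the scaling. Insulin-like peptide genes had 1 of 20 higher and 4 lower (1 and 5 adjusted over the list alone; adjusted p = 0.118), with ins-17 at -1.32 ± 0.55 (0.059 without prep 1), ins-7 at -1.27 ± 0.35 and ins-5 at 1.14 ± 0.60 (0.104, 0.0891 and 0.056 without preps 1, 2 and 4). The rises were 0, 0, 1 and 0 and the falls 2, 3, 4 and 3 without preps 1, 2, 3 and 4. The 2222 features of the X chromosome, which is largely silent in the germ line, had 150 higher and 135 lower (133 and 123 adjusted over the list alone) and a median of 0.10. They did not shift (adjusted p = 0.0916), but did without prep 3 (adjusted p = 0.0224) and with array weights (adjusted p = 0.0365). With an estimated correlation the adjusted p was 0.488. The rises were 45, 53, 249 and 77 and the falls 60, 60, 141 and 85 without preps 1, 2, 3 and 4.

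Across the 34 lists, 7 shifted up and 7 down with the preset correlation, and 0 with an estimated correlation. By fry, which asks whether a list's genes move one way on balance, 6 passed. They were vitellogenins and pharynx (adjusted p = 0.0119 each), oocyte (0.013), sperm proteins and germ line (0.0191 each) and cell cycle (0.0421). The other lists called by camera did not pass by fry, at adjusted p from 0.0715 (body wall muscle) to 0.299 (oxidative phosphorylation).

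The preps differed in how well they matched. Across 19153 features on all 4 arrays, which are not independent replicates, Pearson's r was 0.744 between preps 1 and 2, 0.719 between 1 and 4 and 0.679 between 2 and 4. With prep 3 it was 0.495, 0.572 and 0.498 for preps 1, 2 and 4. Of the tested features, 43.03% had the same sign on all of the 3 or 4 arrays with a value, which an offset shared through the reference or channel order can also bring about, and the median SD over preps was 0.37. The labels give each array a different date, and the grouping of these dates by month was chosen here, before the values were seen, and gives 2 batches of 2 preps each, preps 1 and 2 against 3 and 4. Each batch holds L2 samples only. By limma 0 of 19153 features differed between these batches at an adjusted p under 0.05, the smallest being 0.278, and 1400 (7.31%) had an unadjusted p under 0.05. With the batch as a random block, 3794 features passed in the comparison with the reference. The estimated correlation within batches was -0.133, and a negative one narrows the error of the mean and so raises the count.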

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

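The tests of uneven signal in prep 3 and of exposure of a single prep, and the use of the spread over list members, were chosen only after the results were seen. Each of 154 values (120 genes and 34 lists) was examined for a prep far from the other 3 by the gap to its nearest neighbour relative to the range. Of these, 16 stood apart (10.4%). Prep 3 was the outlying one in 11 of them, prep 2 in 4, prep 1 in 1 and prep 4 in 0. Chance gives about 1 in 20 for independent, normally distributed values. Many of these genes were chosen by their values, belong to the lists and moved together on an array, so that rate is no measure of an excess here.

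In prep 3, dpy-5 was at -0.22 (2.74 to 3.25 in the others), myo-3 at 0.47 (2.38 to 2.77), daf-22 at 0.78 (2.33 to 2.60) and flp-24 at -0.40 (-1.37 to -1.26). The heterochronic genes kin-20 (-0.996), alg-2 (-0.85), blmp-1 (-0.28) and nhl-2 (-1.80) were low in prep 3 and lin-46 (0.57) was high. Also apart in prep 3 were phat-7 at 3.63 (2.94 to 3.00) and the median of the heat shock and oxidative stress list at -0.27 (0.18 to 0.21). In prep 2, hsp-16.1 was at 3.76 (1.08 to 1.15), dpy-17 at 0.29 (-3.34 to -2.75), sdz-28 at -1.58 (-0.70 to -0.54) and the histone list's median at -0.30 (-0.14 to -0.11). In prep 1, hsp-12.6 was at -2.69 (-3.98 to -3.88).

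The weaker correlation of prep 3 with the other preps was weighed as 1 pattern. Offsets shared by runs of neighbouring probes are argued against as the whole cause. After centring these runs, its mean r with the others was 0.527, below the lowest r of the other pairs (0.694). The runs follow the order of the probes in the table, and centring removes only a shared offset. Uneven signal within runs or in scale therefore stays open. Random spot noise is argued against too: where a gene had a pair of probes in different runs, their deviations in prep 3 correlated at r = 0.593 (95% bootstrap interval 0.542 to 0.640, 1251 genes). Another developmental time of prep 3 within the stage stays open, though its test met the bound set beforehand. The abu genes deviated by -2.06 (12 members) from the mean of the other preps, which met that bound. By the bound alone this explanation would have been kept. Molting genes deviated by -1.13, and sperm proteins by 1.28 though L2 larvae hold no sperm. In prep 2, the abu (1.52), vitellogenin (-1.29), sperm protein (-1.14) and oocyte (-1.08) lists deviated too. These values are taken from a mean that includes prep 3. The abu median of prep 2 (2.99) lay near that of prep 1 (2.74), so its deviation partly reflects the low prep 3 median (0.19). Yet prep 2 correlated best with the others (mean r = 0.665). In prep 3 the oocyte (0.39), vitellogenin (0.44), hedgehog-related (-0.36) and numbered collagen (-0.06) lists deviated less. Lists not tied to stage, such as the proteasome (-0.68), also deviated. Intensity-dependent bias and a difference in RNA quality stay open, because no intensities were used, and no label gives the time of collection.

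Low germ line lists beside high muscle and pharynx lists were weighed as another pattern. A smaller germ line share in L2 as the whole cause would raise somatic lists alike, but the muscle list exceeded the neuron list by 0.836 (SD 0.322 over preps, range 0.370 to 1.07). The neuron median is near 0 over members that go both ways, but this explanation needs them all to move like muscle, and the median of their means lay 0.72 below that of muscle, narrowly more than the SD over members (0.61 for neurons, 0.70 for muscle). The pharynx and intestine medians lay 0.19 and 0.51 below that of muscle, within the SDs over their members (0.89 and 1.3). The gap therefore rests on muscle and neurons alone. No intensities were used, so a difference in spot brightness between these lists could not be told apart from one in tissue share. The muscle minus neuron gap met the bound set beforehand for arguing against a germ line share as the whole cause. By that bound alone this explanation would have been argued against. It is left open here, a decision made after the value was seen, because spot brightness could not be told apart. The SD over members describes their spread and is not the error of a list median. A germ line share together with changes inside somatic tissues stays open as a hypothesis, and so does the unknown mixture of the reference. The design, with 1 group, gives no contrast that tests a biological explanation.

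The upward shift of the joint P450 and UDP-glucuronosyltransferase list, which the P450 genes alone did not show, was weighed as well. Exposure of a single prep is argued against with the preset correlation only, since the whole list stayed higher in camera whichever of the 4 preps was left out (highest adjusted p = 0.000318, list medians 0.22 to 0.38). Over all 4 preps the list's call was lost with an estimated correlation (adjusted p = 0.515) and with fry (adjusted p = 0.0826). A larger intestine share could not be decided: the list's median exceeded that of the intestine list by 0.141 (SD 0.248), within the 2 SD that had been set beforehand as what this explanation needs. By that bound alone the explanation would have been kept, and the decision to leave it open was made after the value was seen, because 12 intestine genes rose and 8 fell and their median of 0.16 is small beside the SD over members (1.3).

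For the count of 2936 features, turning the sign of 1 or 2 arrays gives 8 sign patterns, too few for a share under 0.05. The highest count among the other patterns was 0, and 1 pattern, the real one, reached 2936.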

How the results depend on the processing

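Centring within runs of probes and the restriction to features with 1 gene name were chosen after the data were seen. The count of 2936 features stayed within 1.5 times under deposited values (2942), mean centring (2973), scale (3298) and quantile normalization (3361), run centring (2924, with 2457 of the 2936 shared), a robust fit (2912), other minimum numbers of arrays (2990 and 2899), single probes (3100), the filter on extreme ratios (2931), the month as a block (3794) and 1 gene name only (2752). Array weights gave 4218 in all, with 1679 higher, and a test against a fold of 1.5 gave 652 (149 higher, 503 lower), since it asks for a larger change. Leaving out 1 prep gave 1157 to 3202 in all, 285 to 1362 higher and 872 to 1840 lower. Fewer arrays lower the power by construction, yet the count rose without prep 3, and the cause was not tested. In every setting run, 0 calls changed direction. The share of higher calls was 32.97% on the likely direction (67.03% with the ratios turned), and on the likely direction 41.5% with mean centring, 42.5% without prep 3, 24.6% without prep 1 and 22.85% against a fold of 1.5. Of the 14 list calls, 0 were kept with an estimated correlation and 6 with fry, and leaving out 1 prep changed the number of list calls by less than 1.5 times. The estimated correlation allows for genes of a list moving together between preps, which 4 arrays measure poorly. Moving together does not account for every lost call. The pharynx list had an estimated correlation of -0.0157, below the preset 0.01, yet its adjusted p in camera went from 2.79e-05 to 0.488. With 3 residual degrees of freedom this test has little power, so a lost call is little evidence that a list did not shift. Named genes gave 1359 values on the same side of the threshold, 175 that lost it, 6 that gained it and 12 that moved without a call. The letters in the array titles, taken here as a print code, were not run as a random block, because the correlation was not estimable. The number of arrays limits the precision, and signal over background was not used here.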

Other observations

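The tests in this part were all chosen after the data were seen. Genes were also grouped by the letters of their names, which gave 183 families with at least 8 members. With the preset correlation 26 families were higher and 13 lower, and 0 passed with an estimated correlation. Chemoreceptor families lay slightly high: all 20 tested had a median above 0 (0.09 to 0.44), 13 of them passed and 0 were lower. Over 1020 chemoreceptor genes the median was 0.26, with 0.16, 0.33, 0.39 and 0.08 in preps 1 to 4, yet only 13 genes were past the threshold and higher and 5 lower. With an estimated correlation the adjusted p of these families was between 0.756 and 0.819. Whether these spots were dim was not examined, since no intensities were used.

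Of 16 skr genes, which encode Skp1-related parts of ubiquitin ligases, 9 fell and 0 rose (median -1.14), and of 52 nlp neuropeptide genes 14 fell and 0 rose (median -0.52). Of 45 ttr transthyretin-like genes 11 fell and 1 rose (median -0.49). Mitochondrial ribosomal proteins lay high, with 7 of 20 mrps genes higher and 1 lower (median 0.48) and 3 of 22 mrpl genes higher (median 0.42). Of 9 hrg genes, which encode heme transporters and related proteins, 4 rose (median 1.39), and in prep 3 that median was -0.07. With an estimated correlation, none of these families passed (adjusted p = 0.756, or 0.757 for nlp).

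Neighbouring probes in the table shared an offset. The medians of the 32 runs of probes spanned 0.481, 0.871, 0.912 and 0.378 in preps 1 to 4, against at most 0.171, 0.200, 0.197 and 0.122 in 100 shuffles of the probe order. Preps 2 and 3, with the widest spans, share the letters SL in their array titles, against SJ and SG for preps 1 and 4. The labels do not say what these letters mean, and a link was not tested.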
